A study of Mus musculus with 12 samples.

How the data were processed

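RNA of mouse bone-marrow-derived macrophages was measured on 12 Affymetrix Mouse430_2 arrays, 3 in each of 4 groups (control, LPS, MVs and MVs-FR), as the labels assign them. The deposited values are log2 signals per probe set, made with RMA in Affymetrix Expression Console 1.2.0.20 per the submitters' processing notes, with 1 column per array. RMA corrects background, applies quantile normalization and summarises probes by median polish, and whether all 12 arrays were run together is not given in the sources used here. The labels' protocols describe RNA integrity numbers above 8.5, random-primed amplification, and fragmented, biotin-labelled DNA. How 3 prime minus 5 prime differences follow RNA quality under random-primed labelling is not given in the sources used here. Whether human RNA carried in the vesicles bound to mouse probes was not tested, since no array held vesicles alone. No detection calls or scan dates were used, since the sources used here give none. Arrays have no read depth, and their number limits the precision: the median SE of a log2 difference was 0.114, with 8 residual degrees of freedom. A change from values at background, or up to values near the top of an array, is a lower bound of its size.

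Gene names came from the annotation of the array, checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6 used for names only. Of 45101 probe sets, 34958 carried a single symbol, 932 several and 9211 none, 64 were control probe sets, and 34754 of the single-symbol ones matched the RefSeq table, while 204 kept the symbol as given. Each of 18193 genes was represented by its probe set with the highest mean over the 12 arrays, with no filter on level, and 9010 genes had more than 1 probe set. The planned unit was written as a transcript cluster, and on this array it is a probe set.

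All 6 contrasts of the 4 groups were fitted with limma 3.58.1 in R 4.3.3, as a model with the group as its only factor on the 12 arrays, followed by empirical Bayes moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p of a gene is from limma. The 19 gene lists and 7 lists of cell type markers were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a contrast, and again with an estimated correlation. The gene lists were inflammatory cytokines, chemokines, NF-kB targets and feedback, type I interferon response, antimicrobial and classical activation, TLR4 pathway components, other pattern recognition receptors, NRF2 antioxidant response, scavenger receptors and lipid handling, engulfment receptors, cholesterol synthesis, cell cycle, alternative activation, glycolysis and hypoxia, heat shock, unfolded protein and integrated stress, immediate early genes, antigen presentation and oxidative phosphorylation. The marker lists stood for macrophages, neutrophils and their precursors, lymphocytes, dendritic cells, erythroid cells, mast cells with basophils, and fibroblasts with stroma, the cells that marrow cultures could hold. Lists, contrasts, tests and alternatives were fixed before the data were examined, except where a choice is described as made later.

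Genes are named by a rule: per contrast the 10 largest rises and 10 largest falls among called genes whose 3 values per group did not overlap, up to 4 called members of each list (or 2 with the smallest p where none was called), and 10 genes in every contrast (Tlr4, Ly96, Cd14, Tnf, Il1b, Il6, Cxcl10, Ifnb1, Nos2 and Hmox1). A gene could also be named in a contrast other than the one that picked it. The rule gave 259 genes and 639 gene and contrast pairs, of which 585 were called, and in 9 of these pairs another probe set of the gene was called the opposite way (Rnf144b, Ikbkg, Scd2 and Sparc).

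Replicate numbers recur in each group, and the labels do not say that a number marks a shared mouse. Arrays with the same number deviated together: all 18 same-numbered pairs between groups correlated above 0.1 in their deviations from the group means (0.209 to 0.528, mean 0.337, against a mean of -0.166 for different numbers), and each of the 12 arrays correlated best with its own number. The pairing is thus read from the data, and a model with the replicate number as a block was run beside the main model.

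Concordance of contrasts was measured across genes with Pearson and Spearman correlations, and for contrasts that share the controls it was set beside 100 simulations of unchanged groups and beside the overlap of independent lists. Splits of 6 arrays into 3 and 3 number 10. The models were tested on simulated data built from the control means and the real residual spreads, with 200 of 18193 genes changed and arrays drawn independently. In the simulated LPS and control groups 41.8% of changes of 0.5 log2 units, 92.5% of 1 unit and 100% of 2 units were recovered, and 4.88% of calls were false. In the simulated MVs and control groups recovery was 37.3%, 89.6% and 98.5% with 5.66% false calls, and in the simulated MVs-FR and control groups 40.3%, 92.5% and 97.0% with 4.38%. In the simulated LPS and MVs groups recovery was 46.3%, 89.6% and 100% with 6.55%. A list shifted by 1 unit in simulated LPS and control groups was the only list of 26 that camera called. Genes were drawn independently of each other in these simulations, so they could not show false list calls that arise from correlated genes. Far fewer genes were changed than limma called for LPS (10115) or MVs (10000) against control, and no effect of the replicate number was built in. Recovery and false calls in the real contrasts may therefore differ from these values.

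Alternatives were centring each array on its median, repeating quantile normalization on the genes tested, leaving out the dimmest 30% of genes, using all probe sets or the mean over the probe sets of a gene, a trended and robust prior, array weights, fitting only the groups compared, treat against a 1.2-fold change, a 2-fold minimum, the replicate block as a fixed or random effect, fry in place of camera, and leaving out each array in turn. Chosen after seeing the data were a model with the actin 3 prime minus 5 prime difference as a covariate, the omission of each replicate number from all groups, and a pairing of arrays by replicate number for the position on the LPS axis and for the difference of the NF-kB and interferon lists. Probe sets without a gene symbol, those of several genes and the control probe sets were left out of the gene tests. A list of 16 calcium and NFAT target genes was written for a single hypothesis test after the main results were seen.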

Results

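Gene expression was measured in 12 arrays of bone-marrow-derived macrophages, cells grown from marrow of male C57BL/6JOlaHsd mice with M-CSF (the growth factor that drives macrophage formation) at 40 ng/ml for 1 week. The 4 groups held 3 arrays each, from cells of 3 mice per group: untreated control, LPS (the endotoxin of Gram-negative bacteria and ligand of the receptor Tlr4) at 100 ng/ml, MVs at 5000 per ml, and MVs-FR at 5000 per ml. MVs were membrane vesicles shed by HEK293 cells (a human embryonic kidney line) under the calcium ionophore A23187, and MVs-FR were such vesicles oxidised further with iron and hydrogen peroxide in the Fenton reaction for 24 h. RNA was taken 4 h after stimulation. No group received buffer or Fenton reagents alone, so each vesicle effect was read against untreated cells. The study's title names Tlr4 as a sensor of oxidative stress carried by partially oxidised vesicles, and the comparisons address how far each kind of vesicle moved macrophage genes as LPS did. Array medians lay between 4.47 and 4.55 on the log2 scale, and the number of arrays limits the precision of every value. Changes are log2 differences ± SE from limma, with 3 arrays per group. Where a gene list has a single count of rises or falls, the count over all genes tested and the count adjusted over the list alone were the same.

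Macrophages given LPS and macrophages given MVs looked alike across genes, and those given MVs-FR stayed close to control. Correlations across genes between arrays ran from 0.982 to 0.988 for LPS with MVs, from 0.988 to 0.995 for control with MVs-FR, and from 0.935 to 0.945 for control with MVs, against 0.992 to 0.996 within groups. On the axis of the 2920 genes changed at least 2-fold by LPS, with the control mean at 0% and the LPS mean near 100%, the MVs arrays sat at 95.1%, 94.8% and 94.5%. The MVs-FR arrays sat at 10.2%, 5.39% and 22.2%, and the controls at -0.32%, -7.14% and 9.27%. Against the control of the same replicate number, a pairing chosen after seeing the data, the MVs-FR arrays lay 10.6, 12.5 and 12.9 percentage points higher. The upper quartile of values was 6.83 ± 0.06 in control, 6.52 ± 0.03 with LPS, 6.52 ± 0.02 with MVs and 6.75 ± 0.04 with MVs-FR (SD, n = 3). The 3 prime minus 5 prime signal of actin was 0.40 ± 0.05, 0.32 ± 0.03, 0.52 ± 0.07 and 0.40 ± 0.01 in that order of groups, and that of Gapdh 0.17 ± 0.02, 0.15 ± 0.02, 0.13 ± 0.01 and 0.24 ± 0.03 (SD, n = 3).

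**Figure D1:**
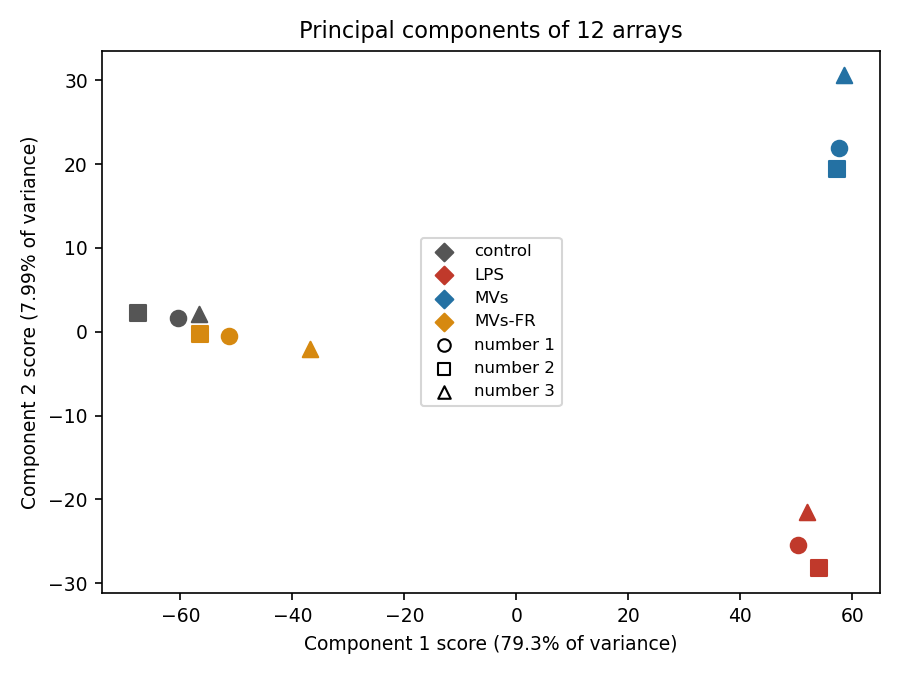
Scores of the 12 arrays on principal components 1 (horizontal, 79.3% of variance) and 2 (vertical, 7.99%), computed from log2 values, with colour for the group and shape for the replicate number. LPS and MVs arrays lie far to the right of control and MVs-FR arrays, and LPS and MVs arrays part on component 2.

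LPS against control shows the response to a Tlr4 ligand. LPS raised Il6, a cytokine of fever and the acute phase, by 8.99 ± 0.72 on the log2 scale (limma adjusted p = 4.7e-07), from control values of 2.81, 2.96 and 5.62 of which 2 lay under the lower quartile of their arrays. It raised Cd69, an early activation antigen, by 8.46 ± 0.22, and Cxcl11 and Cxcl10, chemokines that draw T cells through Cxcr3, by 7.31 ± 0.47 and 6.92 ± 0.63. The gene of Tnf rose by 5.24 ± 0.22 and that of Il1b by 5.21 ± 0.31. Sesn1, a stress-responsive sestrin, fell by 5.98 ± 0.26, Slc40a1, the iron exporter ferroportin, fell by 5.26 ± 0.17, and Cebpa, a myeloid transcription factor, fell by 4.01 ± 0.22. Tlr4 itself fell by 0.98 ± 0.12, while its partners Ly96 and Cd14 rose by 1.07 ± 0.11 and 1.66 ± 0.10.

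All 41 measured members of the type I interferon list rose with LPS, among them the antiviral genes Oasl1 by 5.97 ± 0.25 and Mx1 by 5.57 ± 0.27 (list median 2.74, camera adjusted p = 1.99e-22). All 28 members of the NF-kB list of targets and feedback genes rose too, such as Ptgs2, the inducible prostaglandin synthase, by 6.10 ± 0.35, and Socs3, a brake on cytokine signalling, by 5.36 ± 0.35 (median 2.58, camera adjusted p = 9.67e-22). Of 19 inflammatory cytokines 16 rose, or 18 adjusted over the list alone (median 2.81, camera adjusted p = 1.37e-10). Of 20 chemokines 19 rose and 1 fell (median 4.82, camera adjusted p = 4.87e-10), and of 18 genes of antimicrobial and classical activation 15 rose (median 2.97, camera adjusted p = 2.77e-08). With an estimated correlation the adjusted p of these lists was 0.253 for interferon, 0.0921 for NF-kB, 0.0807 for cytokines, 0.221 for chemokines and 0.253 for antimicrobial genes. Among other pattern recognition receptors 9 of 13 rose and 2 fell, with Nlrp3, the sensor of an inflammasome, up by 3.01 ± 0.19 and Tlr13, a receptor for bacterial RNA, down (-2.72 ± 0.09; list camera adjusted p = 0.00569, and 0.328 with an estimated correlation).

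Falls with LPS included oxidative phosphorylation, cell cycle and scavenger genes. Of 23 oxidative phosphorylation genes 19 fell and 1 rose, led by Sdhb, a subunit of succinate dehydrogenase, at -1.14 ± 0.08 (median -0.53, camera adjusted p = 1.29e-04, and 0.328 with an estimated correlation). Of 32 cell cycle genes 20 fell and 2 rose, or 20 and 3 adjusted over the list alone, including the replication helicase gene Mcm7 at -1.99 ± 0.20 (camera adjusted p = 0.00569, and 0.629 with an estimated correlation). The cell cycle call ended without the dimmest 30% of genes (0.153). Of 21 scavenger receptor and lipid handling genes 15 fell and 2 rose, or 16 and 2 adjusted over the list alone, while Olr1, a receptor for oxidised lipoprotein, rose by 5.20 ± 0.33 (camera adjusted p = 0.00272, and 0.0807 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 23 and fell in 6 (median 0.35, or 0.24 to 0.61 with an array left out, camera adjusted p = 0.0696). In every contrast this list holds Pigq, matched through a synonym in place of the planned Gpi1. That list passed with fry (0.00498), without the dimmest 30% of genes (0.0262) and without control array 3 (0.00542). In the NRF2 antioxidant list 12 of 21 fell and 6 rose, or 13 and 6 adjusted over the list alone. The haem-degrading enzyme gene Hmox1 changed by -1.55 ± 0.11 and the cystine transporter gene Slc7a11 rose by 3.77 ± 0.40 (camera adjusted p = 0.0591). The NRF2 list passed under other scalings, with centred arrays (0.0204) or repeated quantile normalization (0.0301). Macrophage markers showed 11 falls and 3 rises among 19, or 14 and 3 adjusted over the list alone (median -0.41, camera adjusted p = 0.0501). That list passed the test with the replicate number as a block (adjusted p = 0.0180), after repeated quantile normalization (0.00860), without control array 3 (0.0459) and without LPS array 2 (0.0319). In antigen presentation 9 of 19 rose and 1 fell, or 9 and 0 adjusted over the list alone, with the co-stimulatory gene Cd86 up by 2.75 ± 0.21 (camera adjusted p = 0.0253, and 0.761 with an estimated correlation). That call ended with the block (adjusted p = 0.0677), with centred arrays (0.0811), after repeated quantile normalization (0.0511), and without control array 1 (0.0521), control array 2 (0.0649) or LPS array 3 (0.0897).

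Of 18193 genes, limma called 10115 between LPS and control, 4419 higher and 5696 lower with LPS, at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold, 924 were higher and 1996 lower. The 3 LPS values lay clear of the 3 control values for 11247 genes, or 61.8% of genes against 10% by chance. Centring each array on its median moved the median change of all genes from 0.04 to 0.26. It called 13398 genes, 67.1% of them higher, against 43.7% in the deposited scaling, so the balance of rises and falls depended on scaling.

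MVs against control asks what vesicles shed under the ionophore did. MVs raised Il6 by 9.29 ± 0.72 (limma adjusted p = 3.1e-07) from the same controls, Cd69 by 8.47 ± 0.22, Il1a by 7.84 ± 0.31, and Ccl12 and Ccl7, chemokines for monocytes, by 7.54 ± 0.47 and 7.06 ± 0.32. Tnf rose by 6.01 ± 0.22 and Ifnb1, the gene of interferon beta, by 4.49 ± 0.29. Nr4a3, an immediate early nuclear receptor, rose by 6.96 ± 0.32. Sesn1 fell by 6.28 ± 0.26, Lpar6, a receptor for lysophosphatidic acid, fell by 4.46 ± 0.12, and Cebpa fell by 3.86 ± 0.22. Tlr4 differed from control by 0.14 ± 0.12 and was not called (adjusted p = 0.37). It was called higher with each array centred on its median (0.0178) or with the mean over its probe sets (0.0332). Cd14 rose by 1.57 ± 0.10 and Ly96 by 0.59 ± 0.11.

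Every measured member of the interferon list (41), the NF-kB list (28) and the cytokine list (19) rose with MVs, with medians of 2.85, 2.77 and 4.43 (camera adjusted p = 6.89e-22, 1.12e-21 and 7.81e-14). Chemokines rose in 19 of 20 members and fell in 1 (median 5.52, camera adjusted p = 2.42e-11), and antimicrobial genes rose in 13 of 18 (median 2.87, camera adjusted p = 8.09e-07). Other pattern recognition receptors rose in 10 of 13 and fell in 1 (median 0.55, camera adjusted p = 0.00352, and 0.244 with an estimated correlation). Antigen presentation genes rose in 7 of 19 (median 0.16, or 0.11 to 0.54 with an array left out, camera adjusted p = 0.0356, and 0.697 with an estimated correlation). That antigen presentation call ended with the block (0.0599), with centred arrays (0.104), after repeated quantile normalization (0.107), and without control array 1 (0.0711), control array 2 (0.0917) or MVs array 3 (0.0867). For the first 5 lists the adjusted p with an estimated correlation was 0.211 for interferon, 0.0696 for NF-kB, 0.0696 for cytokines, 0.135 for chemokines and 0.238 for antimicrobial genes. A pair of stress lists moved as well. In the unfolded protein and integrated stress list 15 of 18 rose and 1 fell, with Ppp1r15a, which restarts translation, up by 3.31 ± 0.12 and Herpud1, a gene of endoplasmic reticulum stress, up by 2.49 ± 0.11 (median 1.03, camera adjusted p = 6.16e-06, and 0.211 with an estimated correlation). In the immediate early list 15 of 17 rose and 1 fell, with Maff up by 4.28 ± 0.19, Junb by 2.90 ± 0.12 and Egr1 by 2.21 ± 0.15, transcription factors of the early response (median 1.34, camera adjusted p = 1.01e-06, and 0.0696 with an estimated correlation). Of the 3 prime minus 5 prime differences, that of actin was highest in this group (0.52 ± 0.07) and that of Gapdh lowest (0.13 ± 0.01, SD, n = 3).

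Falls with MVs included oxidative phosphorylation, cell cycle and scavenger genes, as with LPS. Oxidative phosphorylation fell in 20 of 23 genes and rose in 2, with Sdhb at -1.32 ± 0.08 and Ndufb8, of respiratory complex I, at -1.24 ± 0.08 (camera adjusted p = 7.62e-06, and 0.211 with an estimated correlation). Cell cycle genes fell in 24 of 32 and rose in 3, or 24 and 4 adjusted over the list alone (camera adjusted p = 0.00141, and 0.497 with an estimated correlation). Scavenger receptor and lipid handling genes fell in 15 of 21 and rose in 2 (median -0.81, camera adjusted p = 0.00530, and 0.0696 with an estimated correlation). Macrophage markers fell in 14 of 19 and rose in 3, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.00877, and 0.497 with an estimated correlation). Without the dimmest 30% of genes the last 3 calls did not hold (0.0727 for cell cycle, 0.0765 for scavenger genes, 0.0807 for macrophage markers). Neutrophil markers fell in 7 of 13, among them the granule protease gene Mmp8 at -2.33 ± 0.51, and the list, not called in the main model, passed with the block (camera adjusted p = 0.173, and 0.00777 with the block). Stroma markers fell in 5 of 9 and rose in 1 (camera adjusted p = 0.424). Dendritic cell markers rose in 4 of 9 (camera adjusted p = 0.0777), and that list passed with the block (adjusted p = 0.0391), with fry (0.0192) and without control array 3 (0.0344). The NRF2 list fell in 12 of 21 and rose in 4, or 13 and 5 adjusted over the list alone, with Hmox1 at -1.33 ± 0.11 and Gclm, of glutathione synthesis, at -1.53 ± 0.13 (camera adjusted p = 0.0356, and 0.378 with an estimated correlation). That call ended with the block (adjusted p = 0.0533), without the dimmest 30% of genes (0.215), without control array 3 (0.0525) and without MVs array 3 (0.0569).

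Between MVs and control limma called 10000 genes, 4222 higher and 5778 lower with MVs, and at least 2-fold 977 were higher and 2267 lower. Values of the groups lay clear of each other for 11178 genes, or 61.4% against 10% by chance. With each array centred on its median, where the median of all genes was 0.28, 13882 genes were called and 67.6% were higher, against 42.2%.

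**Figure D2:**
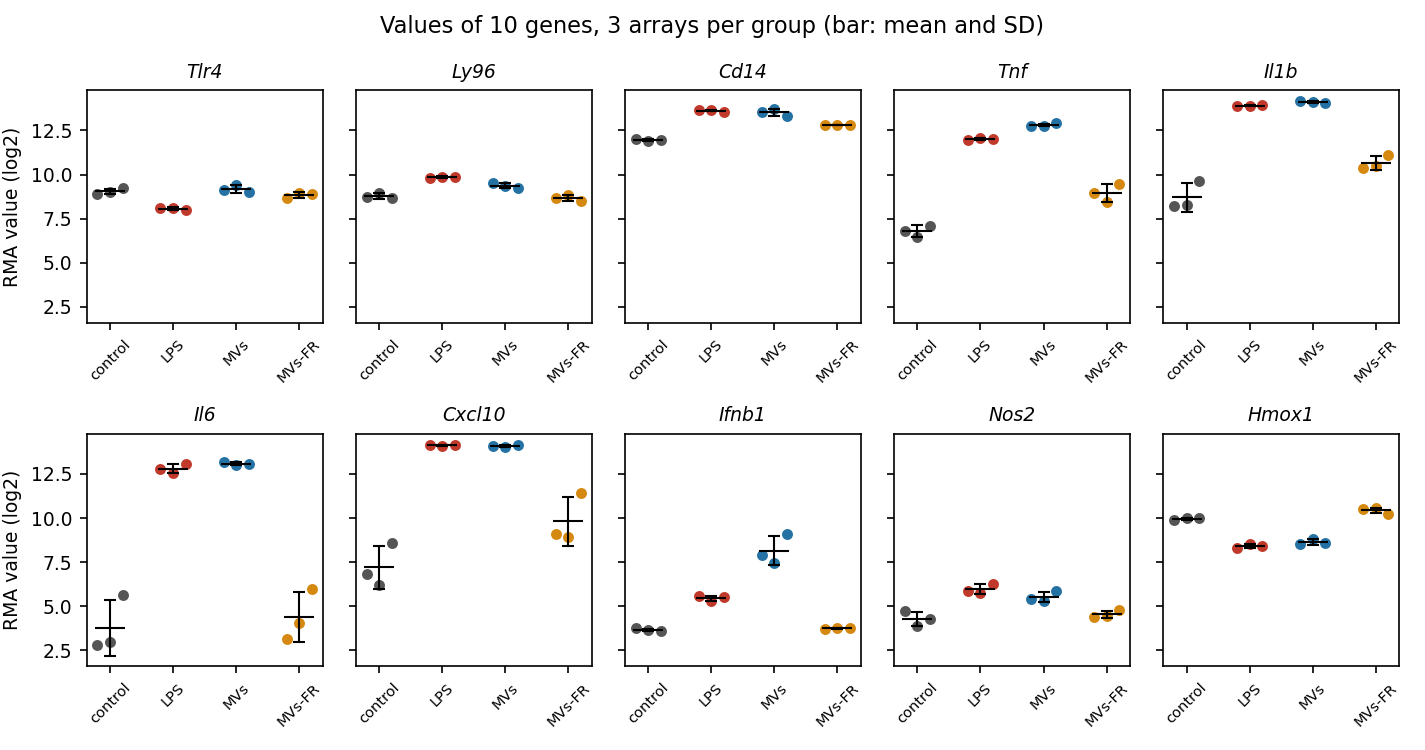
Log2 RMA values (vertical axes) of 10 genes in each of the 4 groups (horizontal axes), with points for the 3 arrays and bars for the mean and SD. Il6 lies near its control level in MVs-FR (0.60 ± 0.72, SE) and far above it in LPS and MVs, while Tnf is raised in MVs-FR by 2.16 ± 0.22 (SE).

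LPS against MVs tests where the stimuli parted. Ccl24, a chemokine for eosinophils, was lower with LPS than with MVs by -4.88 ± 0.23 (limma adjusted p = 2.1e-07), Nr4a3 by -4.26 ± 0.32, Il4, a cytokine of type 2 immunity, by -4.17 ± 0.19, and Hbegf, a growth factor of the EGF family, by -4.05 ± 0.24. The cytokine genes Osm (-3.77 ± 0.22), Il3 (-3.46 ± 0.22) and Il23a (-2.97 ± 0.22) were also lower with LPS, as was Ifnb1 (-2.70 ± 0.29). Higher with LPS were Scara3, a scavenger receptor, by 2.35 ± 0.15 and Pdgfrb, a receptor for platelet-derived growth factor, by 1.96 ± 0.29. Tlr4 was lower with LPS by -1.12 ± 0.12, and Il6, Il1b and Cxcl10 differed by -0.29 ± 0.72, -0.20 ± 0.31 and 0.05 ± 0.63, none of them called (adjusted p = 0.86, 0.78 and 0.98). The SE pools the spread of all 4 groups, and the control values of these genes were scattered (Il6 2.81 to 5.62, Cxcl10 6.21 to 8.59). A gene not called here is thus not shown to be equal. Il1b read 13.87 to 13.96 with LPS and 14.05 to 14.15 with MVs, without overlap, and Cxcl10 read 14.03 to 14.14 in these groups. Both genes lay near the array maxima of 14.32 to 14.44, where differences are compressed.

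The stress lists stood furthest apart. In the unfolded protein and integrated stress list 16 of 18 genes were lower with LPS than with MVs and none higher, including Herpud1 (-2.99 ± 0.11), the chaperone partner gene Dnajb9 (-2.20 ± 0.11) and Ddit3, a transcription factor of prolonged stress (-2.14 ± 0.12). The list median was -0.99 (camera adjusted p = 3.02e-18, and 0.0465 with an estimated correlation). In the immediate early list 11 of 17 were lower and 1 higher, or 12 and 1 adjusted over the list alone, with Egr2 at -2.52 ± 0.22 and Egr1 at -2.23 ± 0.15 (median -0.98, camera adjusted p = 6.34e-12, and 0.0331 with an estimated correlation). Actin's 3 prime minus 5 prime difference also parted these groups, at 0.32 ± 0.03 with LPS and 0.52 ± 0.07 with MVs, while that of Gapdh was 0.15 ± 0.02 and 0.13 ± 0.01 (SD, n = 3). Cytokines were lower with LPS in 9 of 19 genes and higher in 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 7.66e-07, and 0.167 with an estimated correlation). Chemokines were lower in 7 of 20 and higher in 0, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00328, and 0.635 with an estimated correlation). The chemokine call ended with fry (0.0814). Cholesterol synthesis genes were lower in 6 of 17, or 7 adjusted over the list alone, with the sterol sensor gene Insig1 at -1.35 ± 0.11 (camera adjusted p = 2.68e-04, and 0.470 with an estimated correlation).

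Few interferon genes were called between LPS and MVs, with 2 of 41 higher with LPS and 2 lower (median 0.21, camera adjusted p = 0.248). In the NF-kB list 4 of 28 were called each way, or 4 higher and 5 lower adjusted over the list alone. Of all genes limma called 15.3% in this contrast. For NF-kB genes the median was 0.00 and the mean -0.05, on opposite sides of 0 (camera adjusted p = 0.393). Genes of alternative activation were lower with LPS in 6 of 13, such as the mannose receptor gene Mrc1 at -1.11 ± 0.20 (camera adjusted p = 0.00365, and 0.615 with an estimated correlation). That call ended with fry (0.0886). Oxidative phosphorylation genes were higher with LPS in 5 of 23 (camera adjusted p = 0.00328, and 0.615 with an estimated correlation). Stroma markers were higher in 3 of 9 (camera adjusted p = 0.0215, and 0.620 with an estimated correlation). That call ended without the dimmest 30% of genes (0.104), with fry (0.0558) and without LPS array 1 (0.0932) or MVs array 2 (0.161). Macrophage markers, higher in 3 of 19, and neutrophil markers, higher in 2 of 13 or 3 adjusted over the list alone, were not called in the main model (camera adjusted p = 0.0946 and 0.0885) and passed with the block (0.0381 and 2.75e-04). Macrophage markers also passed without LPS array 3 (0.0171) or MVs array 2 (0.0164) and after repeated quantile normalization (0.0431), and neutrophil markers without LPS array 2 (0.0233) or MVs array 3 (0.0147) and with centred arrays (0.0477).

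Limma called 2781 genes between LPS and MVs, 1499 higher and 1282 lower with LPS, and at least 2-fold 109 were higher and 332 lower. The balance turned with centred arrays (1292 higher, 1366 lower), all probe sets (2356 and 2449), treat against 1.2-fold (341 and 573) and without MVs array 1 (1038 and 1084). In fits chosen after seeing the data the count was 315 with the actin covariate. Without number 1 in every group it was 874 (338 higher, 536 lower), without number 2 it was 1743 (835 and 908), and without number 3 it was 1897 (920 and 977). Values lay clear of each other for 5453 genes, 30.0% against 10% by chance. Changes against control correlated across genes at 0.914 (Spearman 0.888), where unchanged groups simulated against the same controls gave 0.4998, and their covariance was 0.713 against a simulated 0.0122. Called genes rose with both stimuli in 3112 cases and fell with both in 5012, against 1026 and 1809 for independent lists, and part of that excess may come from the shared controls. Changes that share no array, LPS minus control and MVs minus MVs-FR, correlated at 0.874 across genes (Spearman 0.820), and 93.1% of the genes called for LPS had the same sign in both. Genes are not independent replicates, so no p is given for these correlations.

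**Figure D3:**
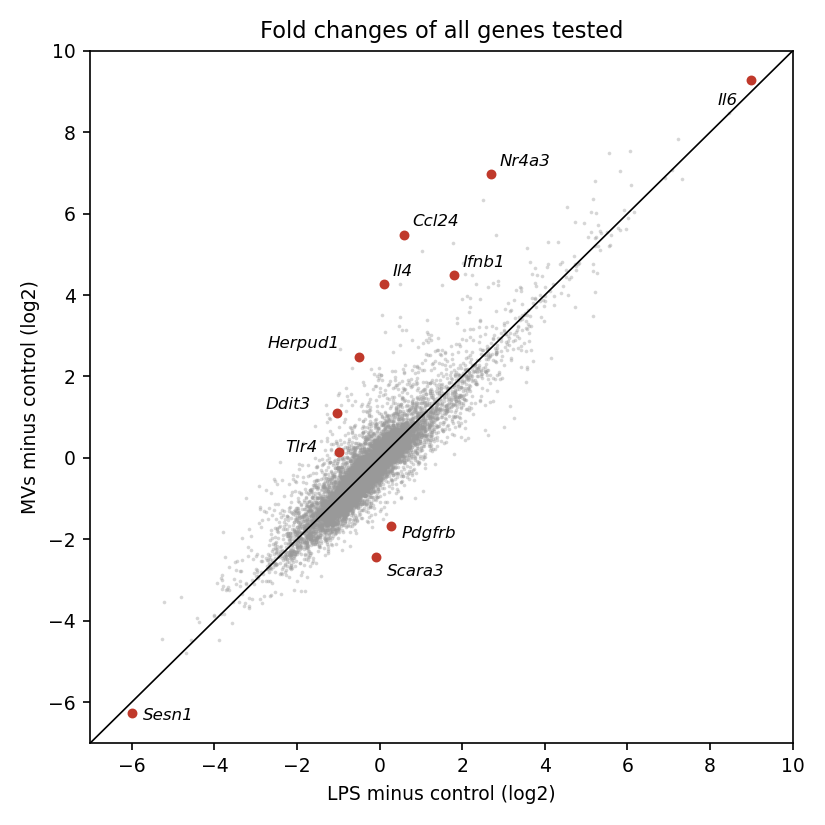
Change with LPS (horizontal, log2, LPS minus control) against change with MVs (vertical, log2, MVs minus control) for 18193 genes, with the line of equal change and 11 genes marked. Points follow the line (r = 0.914), while Ccl24, Nr4a3, Il4 and Herpud1 lie above it, higher with MVs.

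MVs-FR against control asks what remained after the Fenton treatment. MVs-FR raised Cxcl2, a chemokine for neutrophils, by 3.64 ± 0.31 (limma adjusted p = 1.0e-04), Cd69 by 2.50 ± 0.22, Gpr84, a receptor for medium-chain fatty acids, by 2.49 ± 0.27, Nfkbie, an inhibitor of NF-kB, by 2.21 ± 0.17, and Tnf by 2.16 ± 0.22. Tlr2, a receptor for bacterial lipoproteins, rose by 1.78 ± 0.11, and the chemokine genes Ccl3 and Ccl4 by 1.54 ± 0.13 and 1.39 ± 0.15. Among falls were Arrdc3, an arrestin-like regulator, at -1.22 ± 0.16, Abcd2, a peroxisomal fatty acid transporter, at -1.12 ± 0.16, and Rgs2, a regulator of G protein signalling, at -1.09 ± 0.16. Il6 (0.60 ± 0.72), Ifnb1 (0.08 ± 0.29) and Nos2 (0.26 ± 0.21) were not called (adjusted p = 0.81, 0.95 and 0.69). Cxcl10 at 2.60 ± 0.63 was called with the block or without control array 3 (adjusted p = 0.10 in the main model, 0.0202 with the block, 0.0176 without that array), and with array weights (0.0418). Hmox1 at 0.46 ± 0.11 was not called (adjusted p = 0.090), but it was called with the block (0.0389), after repeated quantile normalization (0.0375), with a trended and robust prior (0.0400) and with array weights (0.0195). Il1b rose by 1.95 ± 0.31 (adjusted p = 0.0098), a call that ended without control array 1 (0.0539), control array 2 (0.0560) or MVs-FR array 3 (0.0575), and with only these groups fitted (0.109).

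NF-kB genes rose with MVs-FR while interferon genes were not called. In the NF-kB list 18 of 28 rose and none fell, or 26 and 0 adjusted over the list alone, including Icam1, an adhesion molecule, by 1.81 ± 0.14 and Tnfaip3, a brake on NF-kB, by 1.71 ± 0.16 (median 0.99, camera adjusted p = 6.76e-48, and 0.0281 with an estimated correlation). In the interferon list limma called 0 of 41, and the median was -0.06 (camera adjusted p = 0.618). That list was lower by camera without control array 2 (median -0.18, adjusted p = 0.0306) and without MVs-FR array 3 (median -0.30, adjusted p = 4.54e-12). The mean of the NF-kB list minus that of the interferon list, relative to control, was 1.04 ± 0.33 in MVs-FR (SD, n = 3) against an SD of 0.15 in control, with an exact permutation p = 0.1, the smallest that 3 against 3 unpaired arrays allow. Paired by replicate number, a choice made after seeing the data, it was 1.04 ± 0.24 (SD of 3 pairs, 0.77 to 1.21, exact sign-flip p = 0.25, the smallest possible). In LPS and MVs that difference was 0.10 ± 0.03 and 0.21 ± 0.10 (SD, n = 3).

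Other lists rose in part with MVs-FR. Chemokines rose in 5 of 20, or 10 adjusted over the list alone (median 0.57, camera adjusted p = 9.95e-11, and 0.240 with an estimated correlation). With an array left out the chemokine median ran from 0.36 to 1.09. Antimicrobial genes rose in 5 of 18, or 7 adjusted over the list alone, such as the mitochondrial superoxide dismutase gene Sod2 by 1.32 ± 0.17 (camera adjusted p = 5.21e-08, and 0.383 with an estimated correlation). Cytokines rose in 3 of 19 (camera adjusted p = 0.00392, and 0.493 with an estimated correlation). With fry that call ended (0.0833). The NRF2 list rose in 3 of 21, or 6 adjusted over the list alone, with the autophagy adaptor gene Sqstm1 up by 1.00 ± 0.10, the thioredoxin reductase gene Txnrd1 by 0.92 ± 0.12 and the sulfiredoxin gene Srxn1 by 0.87 ± 0.13 (median 0.20, camera adjusted p = 2.66e-07, and 0.0868 with an estimated correlation). In the TLR4 pathway list 2 of 19 rose, Cd14 by 0.86 ± 0.10 and Ikbke, an interferon-activating kinase, by 0.80 ± 0.10, and that list, not called in the main model, passed after repeated quantile normalization (0.0215). Immediate early genes rose in 2 of 17, or 3 adjusted over the list alone. That list passed with the block (camera adjusted p = 0.0542, and 0.0297 with it) and without control array 3 (0.00771), MVs-FR array 1 (0.0479) or MVs-FR array 2 (0.0104), and after repeated quantile normalization (0.0143). Stroma markers, with 0 of 9 called by limma, were lower with the block (camera adjusted p = 0.211, and 0.0179 with it), without control array 2 (0.0438) and without MVs-FR array 1 (0.0479).

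Limma called 156 genes between MVs-FR and control, 126 higher and 30 lower, and at least 2-fold 47 were higher and 7 lower, while 2125 genes had an unadjusted p under 0.05. Values lay clear of each other for 3133 genes, 17.2% against 10% by chance. The count was 293 (197 higher, 96 lower) with the replicate number as a block, 100 without control array 1, 90 without control array 2, 96 without MVs-FR array 1 and 86 without MVs-FR array 3. In fits chosen after seeing the data it was 10 (all higher) without number 1 in every group and 57 without number 2. Of the 156 genes, 112 rose and 26 fell with MVs as well, against 29.2 and 9.53 for independent lists. The shared controls raise such counts, and in simulated unchanged groups 66.7% of all genes had the same sign. Changes with MVs and with MVs-FR against control correlated at 0.538 across genes. Simulated groups gave 0.4998, but both were unchanged there, while MVs changed 10000 genes. That simulated correlation is therefore no measure of the level without a shared response. The covariance was 0.101 against a simulated 0.0122.

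**Figure D4:**
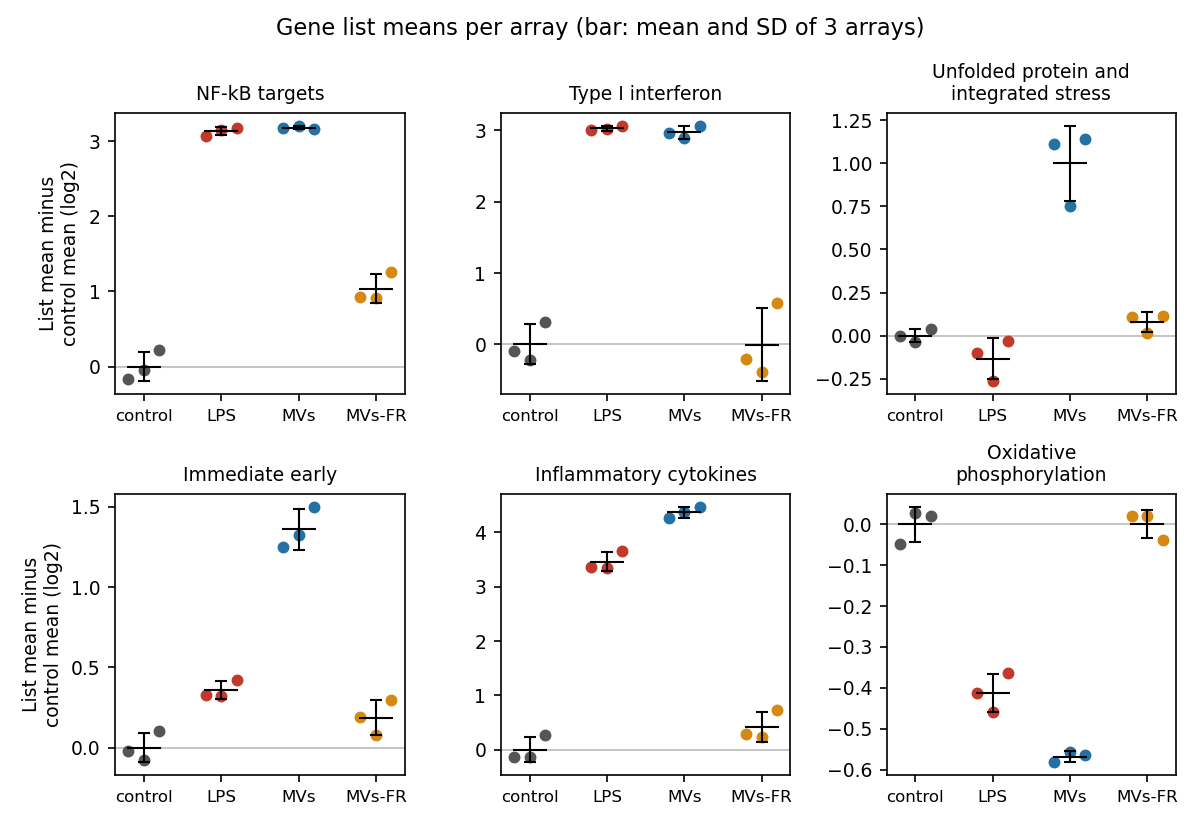
Mean log2 value of 6 gene lists per array minus the control mean (vertical axes) in the 4 groups (horizontal axes), with points for the 3 arrays and bars for the mean and SD. NF-kB targets are raised in MVs-FR (list median 0.99) while interferon genes are not (-0.06), and the unfolded protein and immediate early lists are highest in MVs.

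MVs against MVs-FR compares the vesicles without and with the Fenton treatment, which combined oxidation with 24 h of incubation and reagents that no other group received. MVs gave more Il6 by 8.69 ± 0.72 (limma adjusted p = 6.8e-07), more Il1a by 6.99 ± 0.31, more F3, the tissue factor that starts clotting, by 6.60 ± 0.45, more Tnf by 3.86 ± 0.22 and more Ifnb1 by 4.41 ± 0.29. All 41 interferon genes were higher with MVs, by a median of 2.88 (camera adjusted p = 9.20e-27, and 0.163 with an estimated correlation). NF-kB genes were higher in 27 of 28 (median 1.91, camera adjusted p = 2.93e-19, and 0.0932 with an estimated correlation). Cytokines were higher in 18 of 19, or 19 adjusted over the list alone (median 3.86, camera adjusted p = 8.80e-16, and 0.0496 with an estimated correlation). Unfolded protein genes were higher in 15 of 18 and lower in 1 (camera adjusted p = 4.23e-07, and 0.163 with an estimated correlation). Immediate early genes were higher in 13 of 17 and lower in 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 2.95e-07, and 0.0821 with an estimated correlation). The lower gene was Fos, a partner in the factor AP-1, at -2.23 ± 0.21.

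Lower with MVs than with MVs-FR were the NRF2, oxidative phosphorylation, scavenger, cell cycle and macrophage marker lists. In the NRF2 list 13 of 21 were lower and 3 higher, or 13 and 4 adjusted over the list alone, with Hmox1 at -1.79 ± 0.11, Gclm at -1.81 ± 0.13 and Srxn1 at -1.35 ± 0.13 (median -0.97, camera adjusted p = 0.00160, and 0.168 with an estimated correlation). Oxidative phosphorylation genes were lower in 20 of 23 and higher in 1 (camera adjusted p = 3.53e-06, and 0.168 with an estimated correlation). Scavenger and lipid genes were lower in 15 of 21 and higher in 2 (camera adjusted p = 0.00463, and 0.0821 with an estimated correlation). Macrophage markers were lower in 13 of 19 and higher in 2, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00759, and 0.492 with an estimated correlation). Cell cycle genes were lower in 24 of 32 and higher in 3, or 24 and 4 adjusted over the list alone (median -0.91, camera adjusted p = 0.00336, and 0.492 with an estimated correlation). The calls of the scavenger, macrophage and cell cycle lists ended without the dimmest 30% of genes (0.0638, 0.0750 and 0.0821). Stab1, a scavenger receptor, was lower by -3.15 ± 0.40 and Cebpa by -3.08 ± 0.22. Neutrophil markers were lower in 8 of 13, and that list passed with the block (camera adjusted p = 0.139, and 0.00393 with it), with centred arrays (0.0342) and without MVs-FR array 2 (0.0495). Limma called 8458 genes, 2948 higher and 5510 lower with MVs, and at least 2-fold 911 were higher and 1866 lower. Of called genes 34.9% were higher, against 66.6% of 12501 with each array centred on its median, where the median of all genes was 0.24, and against 45.7% of 8330 after quantile normalization was repeated. Values lay clear of each other for 10067 genes, 55.3% against 10% by chance.

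LPS against MVs-FR shared the interferon, NF-kB and NRF2 differences of MVs against MVs-FR but, by camera, not those of the stress lists. LPS exceeded MVs-FR for Il6 by 8.39 ± 0.72 (limma adjusted p = 1.1e-06), for Cxcl11 by 7.12 ± 0.47 and for Lhx2, a homeobox factor, by 6.22 ± 0.18, while Sesn1 was lower by -5.62 ± 0.26 and Hmox1 by -2.01 ± 0.11. All 41 interferon genes (median 2.74, camera adjusted p = 1.03e-27, and 0.190 with an estimated correlation) and all 28 NF-kB genes (median 1.73, camera adjusted p = 1.30e-19, and 0.119 with an estimated correlation) were higher with LPS. The NRF2 list was lower in 14 of 21 and higher in 3 (camera adjusted p = 0.00112, and 0.190 with an estimated correlation). Unfolded protein genes were higher in 2 of 18 and lower in 7, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.533), and were called lower with fry (0.0300). Immediate early genes were higher in 6 of 17 and lower in 4 (camera adjusted p = 0.151), and were called higher with fry (0.00507). Glycolysis and hypoxia genes were higher in 9 of 23 and lower in 6, or 10 and 6 adjusted over the list alone, with Pfkfb3, which drives glycolysis, up by 3.76 ± 0.17 (camera adjusted p = 0.0359, and 0.716 with an estimated correlation). That glycolysis call ended with centred arrays (0.103) and without LPS array 3 (0.0518). Limma called 8398 genes, 2999 higher and 5399 lower with LPS, and at least 2-fold 861 were higher and 1613 lower. The share higher was 35.7%, against 66.1% of 11934 with each array centred on its median, where the median of all genes was 0.22, and against 45.8% of 8049 after repeated quantile normalization. Values lay clear of each other for 10102 genes, 55.5% against 10% by chance.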

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

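Tests chosen only after their result was seen were the comparison of NF-kB and interferon shares, the mixing estimate, the markers of other cells, the actin covariate and the signed comparison of spikes, which replaced a comparison made without regard to sign. The balance of rises and falls, and the difference between NF-kB and interferon lists in MVs-FR, were not taken up through a direct test. For these lists in MVs-FR the exact permutation p was 0.1 unpaired, and the exact sign-flip p was 0.25 paired by replicate number. Each was the smallest p possible, so these tests could not decide. Other differences below were taken up because the effects of stimuli on the same cells differed by a direct test. Probe sets outside the gene tests were taken up because they carried a signal.

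MVs-FR raised the NF-kB list (median 0.99) while the interferon list stood at -0.0623. A single deviant array is argued against, since without MVs-FR array 3 the NF-kB median was 0.88, 16 members were still called higher and camera gave an adjusted p = 4.65e-52. MVs-FR reached 32.6% ± 6.08 of the MVs value for NF-kB genes and -0.17% ± 17.3 for interferon genes (SD, n = 3), a difference of 32.7 ± 11.4 percentage points, but a weaker MVs stimulus cannot be told apart, because with 1 vesicle dose it is open whether both lists respond alike to dose. RNA of MVs-stimulated cells mixed into these samples is argued against, since it would need a share of 16.9% for the NF-kB median, which predicts an interferon median of 1.03, and the 3 arrays gave -0.44 to 0.40. Whether oxidation spared a vesicle component read through NF-kB more than one read through interferon was not tested. Nor did any group test whether Fenton reagents acted on the cells.

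Unfolded protein and immediate early genes were higher with MVs than with LPS (medians of LPS minus MVs -0.99 and -0.98). Il4, which is in neither list, differed by -4.17. Among 17 markers of mast cells, basophils or lymphocytes the lowest difference was -1.43 ± 0.21 (Cd79b, SE). Their median was 0.01, 1 marker was called higher with MVs, and the highest mean level with MVs was 6.45. A rise of these cells near the size of the Il4 difference was thus not seen. RNA of such cells, present alike in both groups and activated by MVs, cannot be told apart, because their markers would not differ. With actin's 3 prime minus 5 prime difference as a covariate, the unfolded protein median was -0.72 (SE of the list mean 0.20, camera adjusted p = 3.56e-08). The immediate early median moved to -0.47 (SE 0.14, camera adjusted p = 1.79e-05). Both lists kept their camera call. RNA quality still cannot be told apart for either list, because the covariate itself differs between these groups. Calcium entry may contribute, since a list of 16 calcium and NFAT targets was lower with LPS in 9 genes and by a median of -0.84 (camera p = 5.68e-09, and p = 0.00904 with an estimated correlation). The list shares no gene with the unfolded protein and immediate early lists, but it was written after the main results were seen. It includes Nr4a2, Il2 and Il13, relatives of Nr4a3 and Il4, which already differed there, so it is not independent support. Ionophore carried along with MVs and calcium entry set off by the vesicles stay open, and MVs-FR, made from ionophore-treated cells too, changed 0 of these 16 genes by limma (median -0.04).

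Changes of at least 2-fold were mostly falls with LPS and with MVs. An upward shift of 0.27 for LPS and 0.292 for MVs would make rises and falls equal in number, so the scaling of the arrays would have to read treated arrays too low. Spikes gave no such fall, with mean shifts of 0.11 ± 0.11 and 0.15 ± 0.11 for hybridization spikes and 0.01 ± 0.14 and 0.05 ± 0.14 for polyA spikes (SE), though the polyA value with LPS lay just within 2 SE of the shift needed. With LPS, scaling and a true excess of falls cannot be told apart, because the polyA spikes do not exclude the shift needed. With MVs both spike means lay above the downward shift needed by more than 2 SE, which argues against a scaling error of that size there. The balance of all called genes still turned with centred arrays in both contrasts, and no measure of RNA per cell was used here.

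Called in opposite directions by LPS and by MVs, and different between them, were 130 genes, against 2725 for independent lists. The shared controls lower such a count. Some of these genes changed little with 1 stimulus, such as Atp2a2 (-0.20 with LPS) and Prkcsh (0.18 with MVs). How many would stay under another scaling was not tested. Of all lists, 8 differed between LPS and MVs and 15 between MVs and MVs-FR at the preset correlation, of which 2 (unfolded protein and immediate early genes) and 1 (cytokines) were called with an estimated correlation. Medians of LPS minus MVs, each for a list that differed by camera at the preset correlation, were -0.78 for inflammatory cytokines, -0.34 for chemokines, -0.25 for cholesterol synthesis, -0.15 for alternative activation, -0.99 for unfolded protein genes, -0.98 for immediate early genes, 0.16 for oxidative phosphorylation and 0.45 for stroma markers. With an array left out the median ran from -0.55 to -0.24 for chemokines and from -0.41 to -0.09 for alternative activation. Among 9160 probe sets outside the gene annotation, limma called 2890 for LPS against control, 2804 for MVs against control and 44 for MVs-FR against control.

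The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. For genes called, only the real split gave as many in each contrast (1 of 10), and the highest other split gave 0, against 10115 for LPS and control, 10000 for MVs and control, 156 for MVs-FR and control, 8458 for MVs and MVs-FR, 2781 for LPS and MVs, and 8398 for LPS and MVs-FR. For lists called, in the same order of contrasts, 6, 4, 6, 2, 3 and 4 of the 10 splits gave as many as the real 10, 14, 5, 15, 8 and 13, and the highest other splits gave 17, 19, 16, 16, 12 and 16. Every other split mixes the groups 2 to 1, which widens the residual spread. Of these splits 3 part all pairs of same-numbered arrays as the real split does, and their highest were 11, 15, 7, 12, 3 and 10 lists, while the remaining splits put a same-numbered pair on the same side. The correlation of LPS minus control with MVs minus MVs-FR was as high in 2 of 10 splits of the MVs and MVs-FR arrays, at 0.874 for the real split and 0.879 for the highest other. Each other split was signed by its side with more MVs arrays, and so kept part of the MVs minus MVs-FR difference. These splits were thus bound to correlate (lowest 0.707), and they cannot tell whether the real correlation arose by chance.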

How the results depend on the processing

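Tests chosen after the data were seen were the actin covariate and the omission of a replicate number from all groups. Using all probe sets called 20970 (LPS and control), 20749 (MVs and control), 361 (MVs-FR and control), 16847 (MVs and MVs-FR), 4805 (LPS and MVs) and 16712 (LPS and MVs-FR) features, because more features were tested. By construction stricter, treat against 1.2-fold called 5810, 6045, 63, 5505, 914 and 5103 genes in that order, and a 2-fold minimum left 2920, 3244, 54, 2777, 441 and 2474. MVs-FR against control was the least stable count: 277 with array weights, 293 with the replicate block as a fixed effect (all 156 among them), 90 with only these groups fitted, 86 to 170 with an array left out, and 10 and 57 without number 1 or number 2 in every group. LPS against MVs gave 315 with the actin covariate, where the median SE was 0.246 against 0.114, and 874 and 1743 without number 1 or number 2. Apart from fewer arrays in a fit the cause was not tested. Centring arrays or repeating quantile normalization kept each total of genes called within 1.5 times, but centring raised the genes called higher from 4419 to 8993 (LPS and control), 4222 to 9378 (MVs and control), 2948 to 8326 (MVs and MVs-FR) and 2999 to 7888 (LPS and MVs-FR).

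The correlation of LPS minus control with MVs minus MVs-FR was 0.867 after repeated quantile normalization, 0.866 with all probe sets, 0.820 as Spearman and 0.860 to 0.882 with an array left out. That of LPS minus control with MVs minus control was 0.909, 0.888 as Spearman and 0.906 to 0.918, and that of MVs with MVs-FR against control 0.363 to 0.588, lowest without MVs-FR array 3. Lists called with an estimated correlation numbered 0 (LPS and control), 0 (MVs and control), 1 (MVs-FR and control), 1 (MVs and MVs-FR), 2 (LPS and MVs) and 0 (LPS and MVs-FR). With fry, which tests a list without comparing it with other genes, 17 were called for LPS and control and 5 for LPS and MVs. MVs-FR against control gave 8 lists after repeated quantile normalization and 5 to 11 with an array left out. In that contrast camera called the glycolysis list (median 0.13) and the antigen presentation list (0.35) higher without control array 3, against no call and a camera direction of lower with all arrays. Their lowest medians were -0.0734 (without control array 2, not called) and -0.175 (without MVs-FR array 3, called lower). Relative to the control mean, the antigen presentation list mean was 0.55 in control array 3 and 0.49 in MVs-FR array 3. It was -0.20 and -0.34 in control arrays 1 and 2, and -0.18 and -0.32 in MVs-FR arrays 1 and 2. The glycolysis list mean was 0.31 in control array 3, against -0.17 and -0.14 in control arrays 1 and 2. Why arrays numbered 3 read higher was not tested.

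The replicate block ended the calls of the antigen presentation list for LPS and for MVs (0.0677 and 0.0599) and of the NRF2 list for MVs (0.0533). It added alternative activation for MVs (0.0430), the marker and immediate early lists given above, and the genes Arg2, Hp and Tfrc for LPS against MVs and Cxcl10, Hmox1 and Klf4 for MVs-FR, and it changed no other call of a list or named gene. Over all alternatives 7949 results for named genes stayed as they were, called or not called, 331 lost a call, 27 gained one and 0 reversed. For lists 1687 stayed as they were, 105 lost a call, 78 gained one and 2 reversed. Leaving out the dimmest 30% of genes ended 11 list calls and added 6, and the cause was not tested.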

Other observations

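No test in this part was chosen to explain a result; genes named outside the rule are described as such. Among genes raised by MVs-FR, 93 of 126 were higher with MVs than with MVs-FR and 18 were lower. Spic, a transcription factor of iron-recycling macrophages, rose by 1.41 ± 0.19 with MVs-FR and differed by -1.65 ± 0.19 between MVs and MVs-FR. Nr1h3, the nuclear receptor LXR alpha, rose by 0.83 ± 0.12 with MVs-FR against changes of -0.53 ± 0.12 with MVs and -0.44 ± 0.12 with LPS, all called by limma. Nfe2l2, the gene of NRF2 itself, rose by 0.50 ± 0.09 with MVs-FR (adjusted p = 0.0150), while MVs and LPS gave -0.19 ± 0.09 and -0.09 ± 0.09, not called. Spic and Nfe2l2 were chosen after their values were seen.

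Among genes called in opposite directions, 93 rose with MVs and fell with LPS, such as Plekhf1, a lysosomal adaptor, Herpud1, Ddit3, Egr2 and Dnajb9, and 37 did the reverse, such as Tpgs2. Of 16 calcium and NFAT targets, chosen after the main results were seen, 12 rose and 2 fell with MVs. Rcan1, a feedback inhibitor of calcineurin, rose by 2.83 ± 0.14 with MVs and 1.04 ± 0.14 with LPS. With MVs Nr4a2 rose by 1.61 ± 0.21 and Il2 by 1.68 ± 0.22, the latter from a control mean of 2.89, under the lower quartile of the control arrays, to 4.57. The falls with MVs were Nfatc2 at -3.54 ± 0.28 and Nfatc1 at -1.07 ± 0.18. With LPS alone Nr4a2 and Il2 gave 0.00 ± 0.21 and 0.12 ± 0.22, not called.

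With LPS unfolded protein genes rose in 4 of 18 and fell in 7 (camera adjusted p = 0.632), and immediate early genes rose in 6 of 17 and fell in 3 (0.158), a list that was called higher with fry (adjusted p = 2.39e-04). In the TLR4 pathway list 9 of 19 genes rose and 6 fell with LPS (camera adjusted p = 0.0809), with Myd88, the adaptor of the receptor, up by 1.94 ± 0.09, and 9 rose and 4 fell with MVs, or 9 and 5 adjusted over the list alone (0.0777). Engulfment receptors rose in 4 of 16 and fell in 7 with LPS (0.504), among them Cd300a at -2.64 ± 0.13, and rose in 5 and fell in 7 with MVs (0.534). Heat shock genes rose in 3 of 12 and fell in 4 with LPS (0.957), where the median was -0.07 and the mean 0.03, and cholesterol synthesis genes rose in 3 of 17 and fell in 7 (0.450), or 3 and 8 adjusted over the list alone. Lymphocyte markers rose in 1 of 10 and fell in 1 with LPS, or 0 and 1 adjusted over the list alone (0.679), where the median was 0.22 and the mean -0.15. Erythroid markers rose in 1 of 7 and fell in 1 (0.632), and mast cell and basophil markers rose in 1 of 7, or 0 adjusted over the list alone (0.512).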
